A study of Homo sapiens with 6 samples.

How the data were processed

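The deposited table holds whole-number counts per gene symbol for 6 libraries of HUES8 human embryonic stem cells with a conditional DICER1 knockout, 3 grown with and 3 without doxycycline. Per the labels' protocols, total RNA was isolated from sorted cells, libraries were made with a stranded total RNA kit and 6 cycles of PCR, and both ends were read for 50 bases on an Illumina instrument. Per the submitters' processing notes, the tools were Trim Galore 0.4.5, STAR 2.5.3a, HTSeq 0.9.1 and DESeq2, with the genome build hg19. The strand setting, the treatment of reads that match several places and the annotation release are not given in the sources used here. The authors deposited the counts without normalization, 1 column per library, with 55765 symbols. The table has 0 rows that name no gene and 0 columns of other samples, so the share of reads outside genes is unknown.

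Libraries were grouped by the doxycycline label in their titles. Totals ran from 35117961 to 42380004 counts. Mitochondrial genes took between 5.27% and 6.08% of them with doxycycline and between 4.83% and 5.05% without it. Every pair of libraries of a condition differed by more than sampling noise (chi-square per degree of freedom of 3.15 or more), so none was counted as a repeat. This ratio cannot tell separate cultures from separate preparations of the same culture. Replicates 2 and 3 without doxycycline were the closest pair, at 3.15, and the next closest had 19.5. If they shared a culture, the errors of the fit without both replicate 1 libraries are too small. The same replicate numbers appear in both conditions. The deviations of same-numbered libraries from their group means had correlations of -0.024, 0.07 and -0.027 across genes, so the numbers were not taken to pair the libraries. The second principal component placed both replicate 1 libraries on the same side (31.5 and 38.1), so a factor they share is not excluded.

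The main test was edgeR 4.0.16 (quasi-likelihood, robust) in R 4.3.3 on the deposited counts, with TMM scaling, the filterByExpr filter and Benjamini-Hochberg adjustment at 0.05, over 18269 genes. Standard errors are the size of the log2 fold change over the square root of its F statistic. CPM values are TMM-scaled, and a prior count of 2 was used for log2 CPM. Gene lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over 26 lists, and again with an estimated correlation. Camera here used the counts through edgeR. The lists cover microRNA pathway proteins and host transcripts, pluripotency, naive state, NODAL signalling, reported miR-302 and miR-17/92 targets, extrinsic and intrinsic apoptosis, p53 targets, definitive endoderm, mesoderm, neuroectoderm, trophectoderm and amnion, interferon response, S phase, G2 and M phase, cell cycle inhibitors with D cyclins and their kinases, Hippo pathway, epithelial and mesenchymal genes, ATF4 stress response, mitochondrial mRNAs, fibroblast markers, DNA methylation enzymes, histones and ribosomal proteins. They were written before the data were examined, as were the tests and the rule for naming genes. The rule took DICER1, a fixed set of 15 other genes, and the 10 protein-coding genes with the largest rise and the 10 with the largest fall among those with an adjusted p under 0.05, an average log2 CPM of at least 1 and groups that do not overlap. In each list it took every called member where 4 or fewer were called, and otherwise the 2 that rose and the 2 that fell with the smallest p. Since the test on 6 libraries called none, the rule was applied to the fit without both replicate 1 libraries, a choice made after the values were seen. The dispersion falls when the libraries farthest from their groups are left out, so that fit's adjusted p-values are smaller than those of a planned test would be.

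Of the symbols, 33905 matched the GENCODE annotation given as reference directly, 34 by a current and 1334 by an older name, and 20492 did not match. The reference is on another build than hg19, so it gave names, gene types and sequences only, and no coordinates are reported. The 7-mer test used the longest annotated 3′ UTR of at least 50 bases per protein-coding gene. For each 7-mer found in at least 50 genes, the difference in log2 fold change of genes with and without it was estimated with log2 UTR length and GC content as covariates and divided by its standard error, and 7-mers were ranked by this ratio. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for this step, and matplotlib 3.10.9 for the plots.

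On counts simulated for 18269 genes with the means and dispersions of the 6 libraries, the edgeR test recovered 61 of 100 genes changed 2-fold and 95 of 100 changed 4-fold, with 16 false calls, a higher yield than the 0 genes called in the real counts. For 18350 genes and 4 libraries it recovered 96 and 100, with 27 false calls. A simulated 7-mer effect of 0.2 over 14185 genes was estimated as 0.191 and ranked 1, and with no effect the largest ratio over all 7-mers was 3.89. Alternatives covered the scaling (RLE, upper quartile, library totals), the filter (none, or 1 CPM in 3 libraries), DESeq2 1.42.0, limma-voom, a fit that was not robust, a replicate block, a fit without mitochondrial and small RNA genes, each library left out in turn, a test against a fold of 1.5, an adjusted p under 0.01, and for the 7-mer a higher expression minimum of 3 (average log2 CPM), no covariates and coding sequence. After the values were seen, a fit without both replicate 1 libraries, limma-voom with library quality weights and a site score per library were added.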

Results

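Total RNA was sequenced from HUES8, an established human embryonic stem cell line, here in a form in which DICER1 can be switched off. DICER1 is the ribonuclease that cuts hairpin precursors into mature microRNAs. Cultures were kept for 6 days with doxycycline at 2 µg/ml, the condition labelled wild-type, or for 6 days without the drug, the condition labelled DICER1 knockout, and cells positive for the stem cell surface marker Tra-1-60 were sorted before extraction. Each condition had 3 libraries. Counts assigned to genes summed to between 35117961 and 35960860 per library with doxycycline and between 40020500 and 42380004 without it. The labels do not say whether the replicates came from separate cultures, so p-values measure only the spread between these libraries. Doxycycline and DICER1 status changed together in this design, and each difference below is given as the libraries without doxycycline relative to those with it.

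DICER1 was lower in all 3 libraries without doxycycline than in any library with it. Its level was 710.3 ± 372.8 CPM (counts scaled to library size, SD, n = 3) with doxycycline and 65.2 ± 3.94 CPM (SD, n = 3) without it. The libraries with doxycycline spread widely, at 390 CPM in replicate 1, 622 CPM in replicate 2 and 1119 CPM in replicate 3, while those without it lay between 62.9 and 69.8 CPM. Counts per gene symbol cannot tell an intact DICER1 transcript from an edited one, nor the endogenous gene from any introduced copy. They therefore do not measure functional DICER1. The log2 fold change was -3.44 (SE 0.36), with an unadjusted p of 1.32e-05 in edgeR's quasi-likelihood test and an adjusted p of 0.0877. DESeq2 gave the same gene an adjusted p of 2.77e-22. Over 18 alternative settings the adjusted p from edgeR, limma or DESeq2 ran from 2.77e-22 to 0.35, and the fold change kept its sign. Without replicate 1 with doxycycline the log2 fold change was -3.73 and edgeR's adjusted p was 0.0164.

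**Figure D1:**
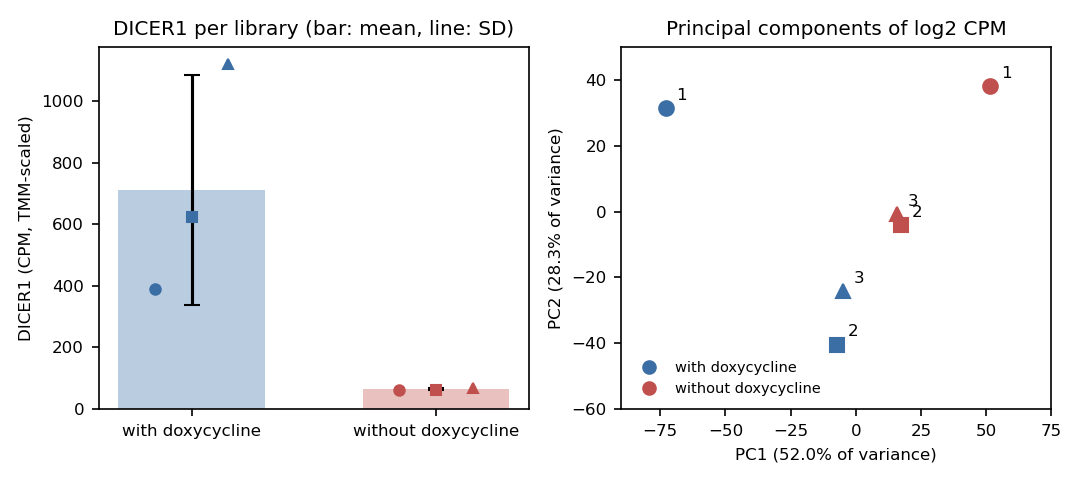
Left, DICER1 in CPM for each library, with the mean as a bar and the SD as a line (n = 3 per condition); right, the first and second principal components of log2 CPM, in arbitrary units, with replicate numbers beside the points. The libraries without doxycycline sit between 62.9 and 69.8 CPM, and replicate 1 of each condition lies apart from the other libraries on PC1, at -72.8 with and 51.7 without doxycycline. On PC2 both replicate 1 libraries lie on the same side, at 31.5 with and 38.1 without doxycycline, and the other libraries between -40.4 and -0.854.

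Across 18269 genes, edgeR's quasi-likelihood test with all 6 libraries called 0 genes at an adjusted p under 0.05. At an unadjusted p under 0.05 it listed 3233 genes, 1838 higher and 1395 lower without doxycycline. With 1 library left out these counts ran from 1842 to 4420, from 1157 to 2549 and from 685 to 1871. With upper quartile scaling in place of TMM that split turned to 1527 higher and 1826 lower. DESeq2 on the same 6 libraries called 748 genes, 553 higher and 195 lower, and limma-voom called 0. Groups did not overlap in CPM for 5399 genes, 29.6% of those tested, where chance gives 10%. Replicate 1 stood apart in both conditions: the SD of its log2 differences from the other libraries of its condition was 0.742 and 0.680 with doxycycline, against 0.367 between the remaining pair, and 0.502 and 0.517 without doxycycline, against 0.266. An edgeR fit without both replicate 1 libraries, chosen after the values were seen, had a dispersion of 0.0055 against 0.0456 and called 1383 of 18350 genes, 1010 of them higher. Of the genes called by DESeq2, 569 were called in that fit too, all 569 in the same direction. The DESeq2 fit contains the libraries of the other fit, so a shared direction is nearly fixed in advance. Leaving out replicate 1 with doxycycline alone gave 5 called genes in edgeR. They were DICER1, FOS, BNC1, TRIB3 and PIK3AP1, the last of which was named after its values were seen. Below, "rose" and "fell" refer to an adjusted p under 0.05 in the fit of 4 libraries, 2 per condition, and the fold changes beside these words are from it unless another fit is named.

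The rule for naming genes was fixed before the data were examined. It named none from the 6 libraries, and from the 4 libraries it took the 10 genes that rose most and the 10 that fell most among 912 that passed it. Those that rose were DACH1, a transcriptional repressor of the Dachshund family, at a log2 fold change of 1.81 (SE 0.18), BNC1, a zinc finger protein of epithelia, at 1.79 (SE 0.09), ZEB2, a repressor of E-cadherin, at 1.69 (SE 0.19), and GFRA1, the co-receptor for the growth factor GDNF, at 1.66 (SE 0.08). They were followed by SYT16, PAPPA, NRCAM, TBX3, CYBRD1 and SCN1B, between 1.61 and 1.44. GFRA1 stood at 14.1 ± 4.58 CPM with and 67.3 ± 25.5 CPM without doxycycline (SD, n = 3). After DICER1, the genes that fell most were FOSB at -1.60 (SE 0.11), GALNT16 at -1.44 (SE 0.12), FOS at -1.20 (SE 0.07) and EGR1 at -1.13 (SE 0.09). FOS, FOSB and EGR1 are immediate-early transcription factors. ROR2, a receptor for WNT5A, fell with -1.06 (SE 0.07), followed by SH3BGR, HSD11B2, ARHGAP18 and TCN2, between -1.04 and -0.93. FOS stood at 166 ± 18.7 CPM with and 74.2 ± 3.95 CPM without doxycycline (SD, n = 3). DESeq2 on all 6 libraries, which include those 4, called 19 of these 20 genes and gave no adjusted p for PAPPA. With all 6 libraries the log2 fold changes of DACH1 and PAPPA were 3.50 (SE 0.80) and 3.50 (SE 0.96), and that of ZEB2 was 3.05 (SE 0.67), so their size rested on replicate 1.

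**Figure D2:**
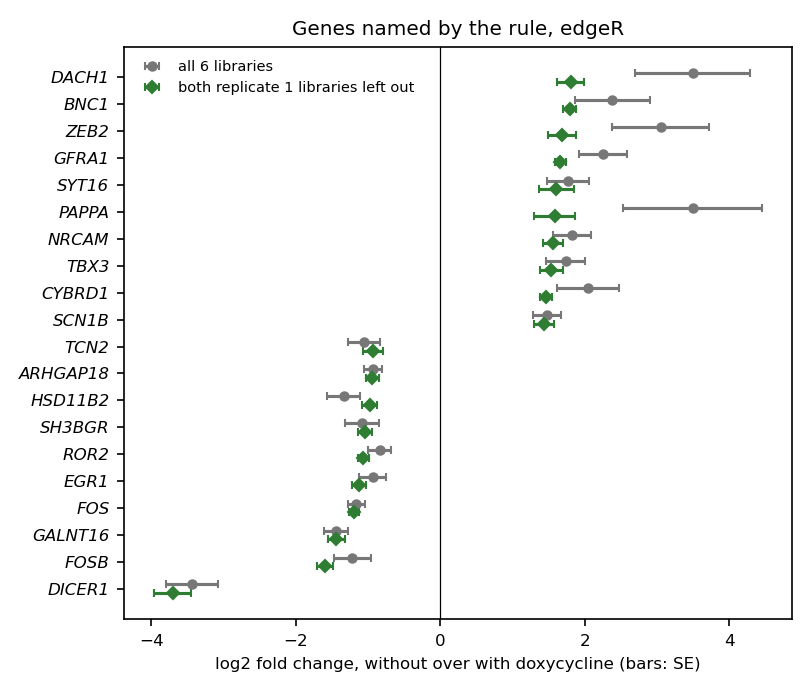
Log2 fold change without over with doxycycline for the 20 genes named by the rule, from edgeR on all 6 libraries (circles) and without both replicate 1 libraries (diamonds), with the standard error as a bar. Both fits place the same 10 genes above 0 and the same 10 below. The rule fixed this in advance, since it took only genes whose groups do not overlap over all 6 libraries. DACH1, PAPPA and ZEB2 differ most between the fits.

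In the list of extrinsic apoptosis genes, 5 of 16 measured members rose, 0 fell and 11 did not pass. TNFRSF10D, a decoy receptor for the death ligand TRAIL, rose by 1.02 (SE 0.07), TNFRSF10B, a TRAIL death receptor, by 0.66 (SE 0.07), and FAS, the receptor of FAS ligand, by 0.79 (SE 0.10), with TNFRSF21 and TNFRSF10A making up the 5. With all 6 libraries FAS stood at 6.97 ± 1.75 CPM with and 19.5 ± 9.97 CPM without doxycycline, and TNFRSF10B at 110.4 ± 8.73 and 255 ± 155 CPM (SD, n = 3). DESeq2 called the same number, 5 of 16, and edgeR on 6 libraries called 5 when adjusted over the list alone and 0 over all genes. Camera, a test of a list against all other genes, called the list higher in the 6 libraries (adjusted p = 7.96e-05 with the preset correlation), but not with an estimated correlation (adjusted p = 0.524). The list's median deviation from the mean of the 6 libraries was 0.54 in replicate 1 without doxycycline, against 0.06 and 0.08 in the other libraries without it.

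Targets of p53 overlapped with these receptors. In that list 8 of 29 members rose and 1 fell, with 11 and 2 when adjusted over the list alone. TNFRSF10B and FAS had the smallest p among those that rose, CDKN1A, an inhibitor of cyclin-dependent kinases, rose by 0.59 (SE 0.10), and PMAIP1, which encodes the BH3-only protein NOXA, fell with -0.30 (SE 0.07). Camera called the list higher in the 6 libraries (adjusted p = 0.0078), not with an estimated correlation (adjusted p = 0.753), and not without replicate 3 with doxycycline (adjusted p = 0.123) or replicate 1 without it (adjusted p = 0.494). The median of this list was 0.40 above the other libraries of its condition in replicate 1 with doxycycline and 0.77 above them in replicate 1 without it. CDKN1A had a log2 fold change of 0.39 (SE 0.42) with all 6 libraries and -0.01 without replicate 1 without doxycycline. In the list of intrinsic apoptosis genes, 3 of 24 rose and 2 fell, and camera did not call it (adjusted p = 0.966; 0.982 with an estimated correlation). BCL2L11 rose by 0.51 (SE 0.09) and APAF1, the scaffold of the apoptosome, by 0.45 (SE 0.09), while BAK1 fell with -0.46 (SE 0.07), as did PMAIP1. In 6 libraries BCL2L11 had 0.74 (SE 0.54), and it ran from -0.061 to 1.308 with 1 library left out. DESeq2 called 0 members of that list, and edgeR on 6 libraries called 0 when adjusted over the list alone.

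In the definitive endoderm list 4 of 13 rose and 0 fell. These were LHX1 at 1.04 (SE 0.20), EOMES at 1.41 (SE 0.27), CER1 at 0.38 (SE 0.09) and CXCR4 at 0.64 (SE 0.15), and 7 members passed in edgeR on 6 libraries when adjusted over the list alone. In the mesoderm and primitive streak list 4 of 11 rose and 0 fell: WNT5A at 0.73 (SE 0.08), MIXL1 at 0.92 (SE 0.15), HAND1 at 2.15 (SE 0.41) and BMP4 at 0.43 (SE 0.10). In the trophectoderm and amnion list 6 of 13 rose and 0 fell, led by TBX3 at 1.54 (SE 0.16) and IGFBP3 at 0.70 (SE 0.08). HAND1 and TBX3 stand in more than 1 list. Levels differed between these genes: EOMES stood at 1.51 ± 0.646 and 10.6 ± 9.76 CPM, TBX3 at 1.81 ± 0.225 and 6.03 ± 1.89 CPM, and CER1 at 50.1 ± 27.8 and 138.3 ± 91.7 CPM, with and without doxycycline (SD, n = 3). GATA6 had a log2 fold change of 2.73 (SE 0.94) in all 6 libraries and 0.76 (SE 0.34) in 4, and the brachyury gene T had 2.82 (SE 0.78) and 1.22 (SE 0.33). Neither gene passed edgeR's test in either fit, and DESeq2 gave GATA6 an adjusted p of 0.019. Camera called the endoderm (adjusted p = 9.77e-05), mesoderm (0.00159) and trophectoderm (1.87e-06) lists higher in the 6 libraries, and none with an estimated correlation (adjusted p = 0.524 for each). The endoderm list's median deviation was 1.76 in replicate 1 without doxycycline, against 0.28 and -0.01 in the other libraries without it. The mesoderm list's was farthest from 0 in replicate 1 with doxycycline (-1.17), at 0.77 in replicate 1 without it, and the trophectoderm list's was -0.68 in replicate 1 with doxycycline, against -0.23 and -0.10 in the others with it, and 0.38, 0.24 and 0.32 in the 3 libraries without it. Of 11 neuroectoderm genes, 1 rose, ZIC2 at 0.79 (SE 0.08), and PAX6 had -0.31 (SE 0.29) in 6 libraries. Camera did not call that list (adjusted p = 0.264; 0.524 with an estimated correlation).

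In the list of epithelial and mesenchymal genes 3 of 14 rose and 0 fell, namely ZEB2, ZEB1 at 1.15 (SE 0.23) and FN1, which encodes fibronectin, at 0.75 (SE 0.11). The other 11, among them the mesenchymal genes CDH2, VIM, TWIST1, SNAI1 and SNAI2 and all epithelial genes, did not pass and ran from -0.31 (CLDN6) to 0.28 (CDH2). Camera called the list in the 6 libraries (adjusted p = 0.0024), not with an estimated correlation (adjusted p = 0.524), and not without replicate 1 with doxycycline (adjusted p = 0.0667). Its median deviation was -0.45 in that library and 0.59 in replicate 1 without doxycycline, against -0.02 and -0.04 in the others with and 0.08 and 0.10 in the others without doxycycline. Among 11 measured fibroblast markers, listed because the cells grew on mouse embryonic fibroblasts, 4 rose and 0 fell: COL1A2 at 0.59 (SE 0.07), COL3A1 at 0.93 (SE 0.13), COL1A1 at 0.40 (SE 0.07) and LOX at 0.58 (SE 0.13). Camera called this list too (adjusted p = 0.000198; 0.524 with an estimated correlation). Its median was 0.55 above the other libraries of its condition in replicate 1 without doxycycline and 0.50 below them (-0.50) in replicate 1 with doxycycline. The cells had been sorted for Tra-1-60. The genome build was human, and whether mouse reads were counted under these human genes was not tested. The counts therefore cannot decide on mouse feeder cells.

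Core pluripotency transcripts differed little. POU5F1 (OCT4) stood at 1712 ± 74.0 CPM with and 1691 ± 62.3 CPM without doxycycline, and NANOG at 57.3 ± 6.43 and 56.0 ± 3.73 CPM (SD, n = 3). Their log2 fold changes in the 6 libraries were -0.02 (SE 0.10) and -0.03 (SE 0.12), and that of SOX2 was -0.31 (SE 0.15). Of 22 pluripotency genes, 1 rose, FGF2 at 0.68 (SE 0.08), 1 fell, ZFP42 at -0.31 (SE 0.07), and 20 did not pass. In 6 libraries 15 of the 22 lay below 0 and 7 above. Farthest on each side were TDGF1 at -0.75 (SE 0.24) and FGF2 at 0.71 (SE 0.11). Camera did not call the list (adjusted p = 0.448; 0.787 with an estimated correlation). Of 11 naive-state markers, TBX3 alone rose and 0 fell (camera adjusted p = 0.921; 0.967 with an estimated correlation); the list's median was -0.24 and its mean -0.01 in 6 libraries while the test leaned upward. In the NODAL list CER1 rose, 1 of 16 members (camera adjusted p = 0.508; 0.710 with an estimated correlation). The NODAL antagonists LEFTY1 and LEFTY2 had log2 fold changes of 0.70 (SE 0.26) and 0.10 (SE 0.37) in 6 libraries and 0.32 (SE 0.10) and -0.24 (SE 0.10) in 4, none called. They are close copies of each other, so the counting could have split their reads. In the list of interferon and double-stranded RNA responses, 1 of 16 rose, the RNA sensor DDX58 (RIG-I) at 0.71 (SE 0.07), and 1 fell, IFIT3 at -0.71 (SE 0.15), while IFIT1 had -0.84 (SE 0.30) in 6 libraries. Camera gave that list an adjusted p of 0.704, and 0.787 with an estimated correlation.

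Of 20 reported miR-302 targets 8 rose and 0 fell, with 9 and 0 when adjusted over the list alone. KDM1B, a histone demethylase, rose by 0.88 (SE 0.11) and BTG2, an antiproliferative factor, by 1.07 (SE 0.17). In 6 libraries BTG2 had 1.49 (SE 0.93), and it ran from -0.118 to 2.68 with 1 library left out. LATS2, a Hippo pathway kinase, had 0.08 (SE 0.21) in 6 libraries and -0.08 (SE 0.07) in 4. Of 17 reported miR-17/92 targets 5 rose and 0 fell, with 8 and 3 when adjusted over the list alone, led by CRIM1 at 0.56 (SE 0.08) and ITGB8 at 0.87 (SE 0.14). Camera called both lists in the 6 libraries (adjusted p = 0.0024 and 0.0253), and neither with an estimated correlation (adjusted p = 0.524 for both). The miR-302 target list's median deviation was 0.47 in replicate 1 without doxycycline, against 0.02 and -0.01 in the other libraries without it and -0.01 in replicate 1 with doxycycline, and the miR-17/92 list's was 0.36, against -0.03 and 0.03. The miR-17/92 list was not called without replicate 2 with doxycycline (adjusted p = 0.0877) or without replicate 1 without doxycycline (adjusted p = 0.129). Both lists overlap with the cell cycle list, which holds inhibitors, D cyclins and the kinases CDK4 and CDK6, and in which 6 of 14 members rose and 0 fell, led by CCND1 (cyclin D1) at 0.52 (SE 0.09) and CDKN1A. Camera did not call that list in 6 libraries (adjusted p = 0.0596; 0.524 with an estimated correlation), but did with a replicate block (0.0464), with no filter (0.0184) and in the fit of 4 libraries (0.00955). With an estimated correlation these were 0.562, 0.271 and 0.398. CCND1 stood at 154 ± 11.6 CPM with and 418 ± 334 CPM without doxycycline (SD, n = 3), with 804 CPM in replicate 1 without it. In the Hippo list 4 of 19 rose, led by STK4 (MST1) at 0.51 (SE 0.08) and TEAD1 at 0.48 (SE 0.10), and CYR61 (CCN1) fell with -0.35 (SE 0.08) but had 0.17 (SE 0.28) in 6 libraries. Camera gave the Hippo list an adjusted p of 0.152, and 0.710 with an estimated correlation. None of 20 S phase genes and none of 20 genes of the G2 and M phases passed edgeR's test, at 6 or 4 libraries. At an unadjusted p under 0.05 there were 0 in the S phase list and 4 in the G2 and M list, and DESeq2 called 0 and 1. Camera gave the lists adjusted p-values of 0.844 and 0.160, and 0.982 and 0.787 with an estimated correlation, and called the G2 and M list lower without replicate 2 with doxycycline (0.0411; 0.746 with an estimated correlation).

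In the list of ATF4-type stress response genes 11 of 20 fell and 0 rose, with 13 that fell and 1 that rose when adjusted over the list alone. TRIB3, a pseudokinase induced by ATF4, fell with -1.20 (SE 0.10), and CHAC1, which degrades glutathione, with -0.82 (SE 0.08). DESeq2 called 2 of 20, both lower. In replicate 1 with doxycycline the list's median deviation was -0.22, against 0.27 and 0.22 in the other libraries with the drug and between -0.17 and -0.11 in those without it. Camera called the list lower in the 6 libraries (adjusted p = 0.0182), not with an estimated correlation (adjusted p = 0.710), and not without replicate 2 or 3 with doxycycline (adjusted p = 0.216 and 0.121) or replicate 2 or 3 without it (adjusted p = 0.129 and 0.155). Of 13 mitochondrially encoded mRNAs 2 fell, MT-ATP8 at -0.58 (SE 0.08) and MT-ATP6 at -0.56 (SE 0.11), which overlap on the same strand, so that reads in the overlap cannot be assigned to either. Camera called that list lower (adjusted p = 0.00712; 0.524 with an estimated correlation), but not without replicate 2 with doxycycline (adjusted p = 0.0952). Ribosomal protein mRNAs shifted by a small amount: the median log2 fold change of 83 genes was -0.32 in 6 libraries, 79 were below 0 and 4 above. In the fit of 4 libraries RPL36A, RPL26, RPS10 and RPS15 fell and 0 rose, at -0.60 (SE 0.09), -0.48 (SE 0.10), -0.49 (SE 0.11) and -0.45 (SE 0.11). In 6 libraries RPL36A had -0.13 (SE 0.27), and it ran from -0.367 to 0.028 with 1 library left out. Adjusted over the list alone, edgeR called 47 in 6 libraries. Camera called the list (adjusted p = 9.81e-19; 0.524 with an estimated correlation). Ribosomal protein genes have many processed pseudogenes, so their counts depend on how shared reads were treated.

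The remaining lists concern the microRNA pathway itself and chromatin. Among 16 microRNA pathway proteins DICER1 fell and AGO1, an Argonaute protein, rose by 0.50 (SE 0.09), as did TNRC6A, a partner of Argonaute, by 0.62 (SE 0.13); the list's median was 0.05 and its mean -0.10 in 6 libraries. MIR17HG, the host transcript of the miR-17/92 cluster, fell with -0.89 (SE 0.12), from 9.57 ± 2.83 to 4.15 ± 0.21 CPM (SD, n = 3), and LINC00925, the host of MIR9-3, rose by 1.96 (SE 0.47) from under 1 CPM. These were the 2 of 12 measured host transcripts that passed, and the host gene MIR302CHG was not found in the table under that symbol. One of 8 DNA methylation enzymes rose, TET1 at 0.62 (SE 0.14), and 1 of 25 replication-dependent histone genes, HIST1H2AC at 0.82 (SE 0.11), which belongs to a family of near-identical copies. Camera called none of these lists in 6 libraries, with adjusted p-values of 0.966, 0.966, 0.508 and 0.225 in the order given, and 0.982, 0.982, 0.787 and 0.787 with an estimated correlation. It called the histone list with the strict filter (adjusted p = 0.0432) and without replicate 1 without doxycycline (0.0107), neither with an estimated correlation (0.55 and 0.649). In all, camera called 12 of 26 lists with the preset correlation, 9 higher and 3 lower, and 0 with an estimated one. The estimate comes from the same 6 libraries and leaves the test few degrees of freedom. Camera's unadjusted p for the ribosomal protein list, for example, went from 3.77e-20 to 0.156. The lack of calls with an estimated correlation therefore does not show that the lists were unchanged.

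**Figure D3:**
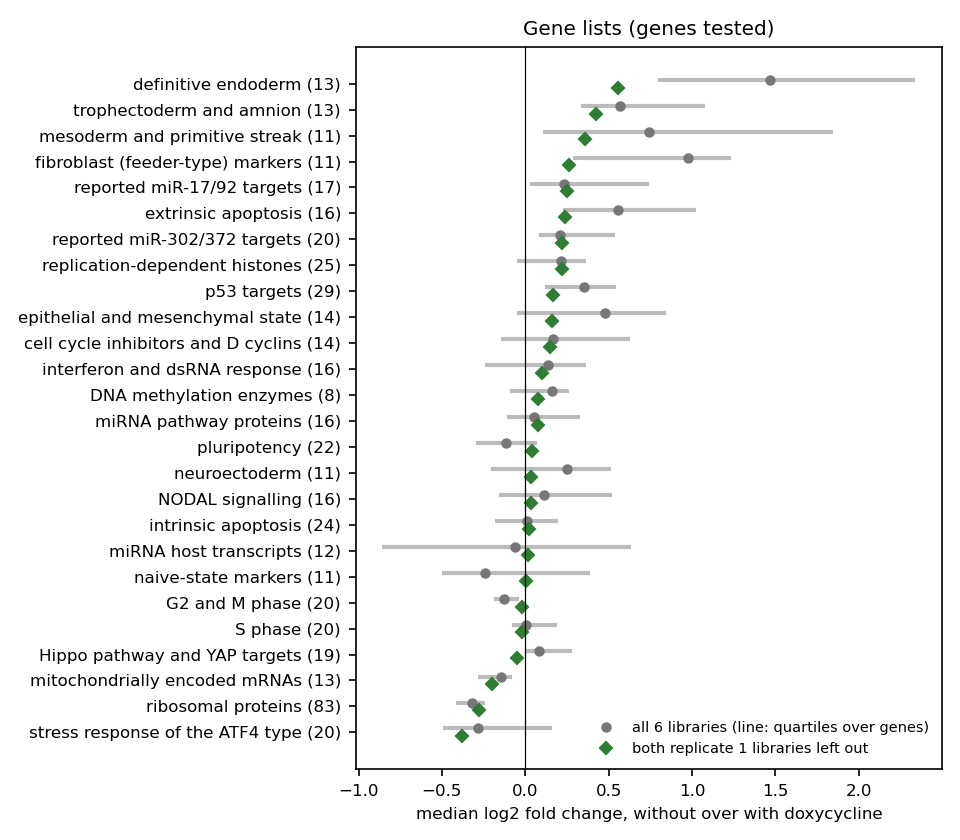
Median log2 fold change without over with doxycycline for each of the 26 gene lists, with the number of genes tested in parentheses, from all 6 libraries (circles, lines are quartiles over genes) and without both replicate 1 libraries (diamonds). The endoderm list has the highest medians (1.47 and 0.56), and the ribosomal protein and ATF4 lists lie below 0 in both fits.

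Genes that carry a match to the miR-302 seed in the 3′ UTR were slightly higher without doxycycline. The 7-mer AGCACTT, which pairs with the seed of the miR-302 family, occurred in the longest annotated 3′ UTR of 3519 of 14185 genes. The median log2 fold change was 0.06 in genes with it and -0.04 in genes without it. After adjustment for UTR length and GC content the difference was 0.04 (SE across genes 0.01), which ranked 81 among 16274 7-mers. Its ratio to the SE was 3.74, below the largest ratio of any 7-mer in a simulation with no effect (3.89). That simulation drew noise independently for each gene. In the real fold changes, 7-mers that share no 6 successive bases with a fixed site of a stem cell family reached 7.35 (TATTTAT) and -8.37 (TACAGGC). A ratio above 3.89 therefore does not by itself set a site apart in these data. Among genes with an average log2 CPM of at least 3 the difference was 0.06, the ratio 7.48 and the rank 6, and without both replicate 1 libraries the ratio was 5.16. Genes are not independent replicates, so these ranks are descriptions. The rank was 141 without replicate 1 and 169 without replicate 3 with doxycycline, and 27 without replicate 1 without it. The sites of some other families fixed as stem cell families ranked higher, with TTTGCAC of miR-19 at 3, TTGCACT of miR-130 at 15 and GCACTTT of miR-17 at 19, and with 1 library left out at 3 to 4, 10 to 21 and 8 to 34. GTGCAAT of miR-25/92 ranked 197 (88 to 2170 with 1 library left out), CAGTATT of miR-200b 1437 (667 to 3258), ATAAGCT of miR-21 2239 (1812 to 3077), CAGTGTT of miR-141 8944 (6072 to 10879), CTACCTC of let-7 15102 (14083 to 15142) and GTTTGAG of miR-371-5p 15372 (11210 to 15869). The comparison sites of microRNAs of other tissues ranked 469 (miR-124), 1709 (miR-1) and 4203 (miR-122), and with 1 library left out 431 to 1361, 1332 to 2163 and 1946 to 7546. Of the 10 highest 7-mers 7 shared at least 6 successive bases with a fixed site of a stem cell family, against 0.725% of all 7-mers, a comparison chosen after the ranks were seen. The rest were TATTTAT, CACACAC and ACACACA. Ratios at the low end were of similar size, with TACAGGC at -8.37, TAGCTGG at -8.11 and ATCCCAG at -7.62, against 8.63 for the highest 7-mer, AAGCACT. None of these low 7-mers is a fixed site. Low 7-mers can overlap each other, as GGGATTA and GGATTAC do (-7.6 and -7.59), so they are not separate cases. What they reflect was not tested.

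Each library could also be scored on its own, as the adjusted difference in log2 CPM between genes with and without a site. For miR-302 the score was -0.02 ± 0.01 with and 0.02 ± 0.01 without doxycycline (SD, n = 3), and every library without doxycycline lay above every library with it. The exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow, and p = 0.186 after Benjamini-Hochberg adjustment over the 13 families. The scores of miR-17, miR-19, miR-130, miR-21 and of the comparison sites of miR-1 and miR-124 separated in the same way. Of the 5 extrinsic apoptosis genes that rose, 3 carried AGCACTT and 4 carried GCACTTT, where 7 and 8 of all 16 members did. Of the 10 named genes that rose most, 5 carried each. Of the reported miR-302 targets, 4 of the 8 that rose carried AGCACTT, against 14 of all 20. Among all genes searched, 24.8% carried AGCACTT and 24.9% GCACTTT.

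**Figure D4:**
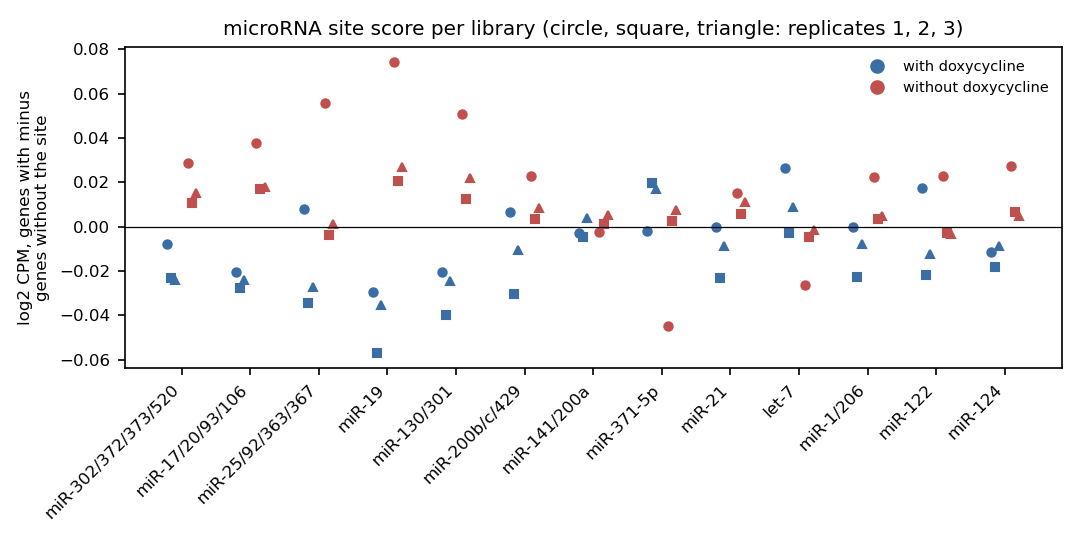
Adjusted difference in log2 CPM between genes with and without each microRNA site in the 3′ UTR, for each library, with doxycycline in blue and without it in red. For miR-302 the libraries without doxycycline sit between 0.0106 and 0.0287 and those with it between -0.0239 and -0.0077.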

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

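The fit without both replicate 1 libraries and limma-voom with library quality weights were added after the data were seen; the other settings were planned. DICER1 kept its direction in 18 alternatives, with log2 fold changes from -3.76 to -2.96. It passed the threshold in 4 of them, at -3.45 in DESeq2 (-3.445), -3.73 without replicate 1 with doxycycline, -3.70 without both replicate 1 libraries and -3.76 with quality weights. With 1 library left out the values ran from -3.73 to -2.96.

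The 0 genes called by edgeR stayed 0 with RLE, upper quartile or library totals, the strict filter, limma-voom, the fit that was not robust, the fit without mitochondrial and small RNA genes, the test against a fold of 1.5 and an adjusted p under 0.01. No filter gave 329 genes (266 higher, 63 lower), DESeq2 748 (553 and 195), the fit without both replicate 1 libraries 1383 (1010 higher and, rounded, 3.7e+02 lower) and quality weights 1431 (934 and 497). The dispersion was 0.0055 without both replicate 1 libraries, against 0.0456 with all 6; for the other 3 counts the cause was not tested. With 1 library left out the count ran from 0 to 5, the higher genes from 0 to 2 and the lower from 0 to 3, and it moved only without replicate 1 with doxycycline.

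Camera called 12 lists, 10 to 12 with 1 library left out, 12 or 13 in the other fits and 0 with an estimated correlation. The cell cycle inhibitor list was gained with no filter (0.0184), without both replicate 1 libraries (0.00955) and without any 1 library of those without doxycycline (0.0191 to 0.0326), the histone list with the strict filter (0.0432) and without replicate 1 without doxycycline (0.0107), and the G2 and M list without replicate 2 with doxycycline (0.0411), none of them with an estimated correlation (0.271 or more). The strict filter ended the call of the ATF4 list (adjusted p = 0.0697). The rank of AGCACTT was 6 among genes with an average log2 CPM of at least 3, 327 with no adjustment for UTR length and GC content, 29 in coding sequence, 55 without both replicate 1 libraries and from 27 to 169 with 1 library left out; the cause was not tested.

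A replicate block left the count at 0 genes, gave 13 lists, the added one being that of cell cycle inhibitors (adjusted p = 0.0464), and a rank of 72, kept DICER1 lower and changed no call of a named gene. The correlations of deviations gave no evidence of pairing, at -0.024, 0.07 and -0.027 for the same numbers. Replicate 1 with doxycycline correlated best with replicate 3 without it (0.075). On PC2 (28.3% of variance), however, both replicate 1 libraries lay together, at 31.5 with and 38.1 without doxycycline. The other libraries lay between -40.4 and -0.854. A factor shared by the replicate 1 libraries is therefore not excluded.

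Of 80 named genes 9 changed sign in some setting, 20 times in all, once past the threshold (CYR61, -0.35 without both replicate 1 libraries). With 1 library left out, POU5F1 ran from -0.05 to 0.016, NANOG from -0.098 to 0.064, LEFTY2 from -0.265 to 0.416, LATS2 from -0.189 to 0.205, CDKN1A from -0.007 to 0.991, BTG2 from -0.118 to 2.68, BCL2L11 from -0.061 to 1.308, CYR61 from -0.135 to 0.34 and RPL36A from -0.367 to 0.028. Without both replicate 1 libraries NANOG had 0.016, LEFTY2 -0.241 and LATS2 -0.076, and with quality weights NANOG had 0.016, LEFTY2 -0.117, LATS2 -0.087 and CYR61 -0.256. In simulated counts 61 of 100 genes changed 2-fold were recovered, but the real fit of 6 libraries called 0 genes, DICER1 at -3.44 included, so the simulation overstates its power and even large changes are not excluded.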

Other observations

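Replicate 1 of each condition differed from the other libraries of its condition in some lists in the same direction and in others in opposite directions. The median of the p53 target list was higher in both, by 0.40 with and 0.77 without doxycycline, and the S phase and histone lists were lower in both (-0.54 and -0.26, and -0.37 and -0.32). The mesoderm list was lower in replicate 1 with doxycycline (-1.06) and higher in replicate 1 without it (0.67), and the pluripotency list went the opposite way (0.25 and -0.32). ACTA2 stood at 17.1 CPM in replicate 1 without doxycycline and at 2.39 and 2.07 CPM in the other libraries without it. These are differences between single libraries, with no test.

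Lists that were higher without doxycycline differed in how many members carry the miR-302 7-mer AGCACTT in the 3′ UTR. It occurred in 0 of 13 definitive endoderm genes, 0 of 14 epithelial and mesenchymal genes and 0 of 11 fibroblast markers, against 7 of 16 extrinsic apoptosis genes and 24.8% of all genes searched. Of the 6 members that rose in the list of cell cycle inhibitors, D cyclins and their kinases, 5 carried it, but of the reported miR-302 targets 4 of the 8 that rose did, against 14 of all 20. These shares were looked up after the fold changes were seen and were not tested.

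In the weighing that follows, the tests of library depth, of group labels and of the edgeR count over other splits, the microRNA site score per library and the fits without replicate 1 were chosen after the result was seen. Replicate 1 with doxycycline stood apart from the other 2 libraries of its condition. Its total was 1.00 times (1.005) their mean and its DICER1 CPM was 5.58 times that of the highest library without doxycycline, which argues against depth and against a wrong label. Mitochondrial rRNA took 0.703% of its counts, against 0.397% and 0.396% in the other 2. A separate batch or preparation of the replicate 1 libraries was not tested. The fibroblast list's median was -0.495 relative to the other 2, so these human genes were not higher as a set. The feeders were mouse cells and the genome build was human, so the list cannot decide on feeder cells. Its miR-302 site score (SE across genes 0.0117) lay 0.0153 above the higher of the other 2, short of the bound of 0.02 written before the score was computed. Comparison sites moved as well. That of miR-122 scored 0.0175 in this library, against -0.0217 and -0.0125 in replicates 2 and 3. The site of miR-1 scored -0.0001, against -0.0225 and -0.0078, while that of miR-124 (-0.0113) lay between the others (-0.0184 and -0.0086). A shift of this size was thus not particular to sites of stem cell families. Weaker microRNA repression remains open as a hypothesis and cannot be told apart from other differences of this library.

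Replicate 1 without doxycycline also stood apart. Its total was 1.04 times (1.045) the mean of the other 2, and its DICER1 CPM was 0.162 times that of the lowest library with doxycycline, so depth and a wrong label are again argued against. More feeder-type or differentiated cells stay open. The fibroblast list's median was 0.545 higher, which met the bound of 0.5 written beforehand. A further condition, that all members be higher than in both others, was not part of that bound, and 9 of 11 were. COL6A3 was lower than in the other 2 (22.0 and 22.2 CPM), and the endoderm list was higher by more (1.52). The sort for Tra-1-60 would remove fibroblasts, and here too the human counts cannot decide on mouse feeder cells. The site score was 0.0135 above the higher of the other 2, again too small a gap to decide on microRNA repression.

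Genes with a miR-302 site were higher without doxycycline, which may reflect loss of repression by these microRNAs. With UTR length and GC content as covariates the site ranked 81, between the bounds of 10 and 100 written before the ranks were computed, and in coding sequence the same 7-mer ranked 29, so base composition stays open for this site. The related sites of miR-17 and miR-130, at 19 and 15 in 3′ UTRs, ranked 2909 and 6222 in coding sequence, while that of miR-19, at 3, ranked 20. The rank reached 169 with 1 library left out and passed 100 in 4 of 6 such fits, but the difference itself stayed between 0.0334 and 0.0397, so neither reading is settled. With 10 splits of 6 libraries no share under 0.05 is possible; the real split gave a difference of 0.0363 and the highest other 0.0242, and 1 split, the real one, was as large.

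The counts of calls were set against the same 10 splits, too few for a share under 0.05. DESeq2 called 748 genes in the real split and at most 0 in the others, so 1 split gave as many. EdgeR called 0 in all 10, with 3233 genes at an unadjusted p under 0.05 in the real split and at most 1419 in the others. Camera called 12 lists in the real split and up to 12 in others, 4 of 10 splits in all, so the list calls with the preset correlation follow other groupings of these libraries as well.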
